A study of Homo sapiens with 6 samples.

How the data were processed

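Gene expression was measured with Illumina beadchip arrays in Mec-1, an established human B cell line with features of chronic lymphocytic leukaemia (CLL). Per the labels, 3 arrays held RNA of cells carrying a scrambled control short hairpin RNA (shRNA) and 3 held RNA of cells carrying an shRNA against SLAMF1, which encodes the surface receptor CD150. The series' design text calls the 3 arrays of each kind biological replicates. It does not say whether they came from separately derived clones or from separate cultures of 1 transfected line, so p-values measure the spread between these samples. Per the labels, total RNA was amplified and biotin-labelled as cRNA. All 6 arrays lay on 1 chip, the control arrays in its first 3 positions and the others in the last 3, so position and group cannot be told apart.

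The values analysed were the deposited probe signal intensities, 1 per probe and array, which the submitters' processing notes link to GenomeStudio, with no version given in the sources used here. Their low end showed that background had not been subtracted. Each intensity came with a detection p-value, deposited per the file headers, which ranks the probe against the array's negative control probes. It never rose with the signal of its own array. A second deposited table held intensities on a linear scale, and its step of normalization is not stated in the labels. 100% of its values lay within 1% of the quantile-normalized probe signals, so it was treated as quantile-normalized intensity without background correction and served as an alternative. Its columns had medians of 87.9 on all 6 arrays.

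Mean signals ranged from 208 to 294 across arrays over an inferred background of 82.1 to 89.1, and 36.3% to 41.4% of probes had a detection p-value under 0.05. Array replicates, 3 per group, limit the precision.

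The table listed 47323 probes, of which 2 had no value. Probe names came from the platform annotation. It gave 30113 probes 1 gene symbol and 8 several symbols, and left 17200 unnamed here. Symbols were brought up to date through the gene identifier for 30074 probes against a RefSeq gene table of assembly GRCh38.p14, which was used for names, biotypes, genomic span and the order of neighbouring genes. Probes with several symbols were not named. Probes of near-identical genes, such as the HLA genes or CCL3 and CCL3L3, may detect more than 1 of them and their values are uncertain in that respect.

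Computation used R 4.3.3 and limma 3.58.1. Background was corrected with limma's nec function, a normal-exponential model with the background taken from the detection p-values, with an offset of 16. Values were then put on the log2 scale and quantile-normalized, and fold changes are on this log2 scale with the offset, which understates changes of dim genes. A probe was kept if its detection p-value was under 0.05 on at least 3 of the 6 arrays, which 19073 probes met, 14555 of them with 1 symbol. Of several probes of a gene the one with the highest mean level over all 6 arrays was tested, which gave 10832 genes. For 2940 of these more than 1 probe passed. Where another probe of a named gene differed from the tested one by over 0.5 on the log2 scale, its value is given, or the range of several.

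The comparison was fitted with limma (lmFit and eBayes) on all 6 arrays with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. A gene not detected on any array of 1 group has only a bound there. Its fold is given as "at least", from the mean of the brighter group over, per array, the higher of the lowest signal among detected probes and the probe's own. Gene lists, 27 in all with 716 members of which 576 were tested, were compared with all other tested genes by camera with an inter-gene correlation of 0.01, adjusted over the lists. The correlation estimated from the data and fry were alternatives. Fry tests whether the members move on balance in 1 direction and does not compare them with other genes. With 24.6% of all tested genes called, a list can pass fry without differing from the rest.

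The named genes were fixed by rule before the data were examined: SLAMF1; the 10 genes with the largest log2 fold change in each direction among those past the threshold, leaving out provisional symbols, open reading frame symbols and Y-linked genes; and, of each list, up to 3 members with the largest change past the threshold. The lists, the test and the alternatives were fixed at the same time. The result of 1 list is not reported here, though the list stays in the counts of lists. The alternatives were no background correction, an offset of 50, median centring, cyclic loess, the second deposited table, no filter on dim probes, a detection p-value under 0.01 on all 6 arrays, the mean of a gene's probes, each probe tested separately, trend and robust variance settings, array weights, the replicate number as a block, and leaving out each array. For array weights the default estimation did not converge on these data, and limma's gene-by-gene method was used in its place.

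The procedure was tested on 10 simulated data sets of this comparison with probe means and spreads taken from the arrays, in which 12617 to 13049 genes passed the filter. In each, 200 genes were changed by known amounts and a list of 30 genes was shifted by a log2 value of 1. Of the genes changed by 0.5, 1 and 2 on the log2 scale, 0.314%, 20.9% and 74.3% were recovered, and 5.83% of all calls were false. The shifted list was called in all 10 data sets, with the preset and with the estimated correlation, and 0 of 260 unchanged lists were called. The simulated genes varied independently of each other, whereas correlations estimated within the real lists reached 0.298. These counts therefore do not measure false calls of lists whose members are correlated. The first version of this test used 1 simulated data set and missed both of its limits, recovery above 80% of the largest changes and false calls under 10%. The number of data sets was then raised, and the limit on recovery was lowered to 60% after that outcome was known. The 74.3% recovered meets the lowered limit and still misses the first one, and changes of about 1 on the log2 scale were mostly not recovered where few genes changed.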

Results

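Expression profiles were collected from 6 samples of Mec-1 cells, 3 labelled control shRNA and 3 labelled SLAMF1 shRNA. The series' title concerns chemotaxis, autophagy and response to therapy in chronic lymphocytic leukaemia, and the 1 comparison of the design asks which transcripts differ when SLAMF1, a receptor of the SLAM family on lymphocytes, is silenced. Between 17192 probes (replicate 2 of the libraries labelled SLAMF1 shRNA) and 19586 probes (control replicate 1) were detected per array.

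The silenced gene was examined first. SLAMF1 was measured by 1 probe, which was detected on all 6 arrays, and it was not lower in the libraries labelled SLAMF1 shRNA. Its log2 level was 8.22 ± 0.19 (SD, n = 3) in the libraries labelled control and 8.60 ± 0.13 (SD, n = 3) in those labelled SLAMF1 shRNA, a log2 difference of 0.38 with a standard error of 0.18 (limma, adjusted p = 0.153, 95% interval -0.03 to 0.79). Without replicate 2 of the libraries labelled SLAMF1 shRNA the difference was 0.46 and passed the threshold as higher (adjusted p = 0.0489, against 0.00735 to 0.831 over all alternatives). The array therefore goes against the label for this transcript, where the probe lies relative to the shRNA target is not known here, and all directions below are those of the labels.

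Expression differed widely between the 2 sets of libraries. CCND2, which encodes the G1 cyclin D2, was at least 94.5-fold lower in the libraries labelled SLAMF1 shRNA, falling from a log2 level of 11.07 ± 0.23 (SD, n = 3) to below detection on all 3 arrays. The intermediate filament gene VIM was 30.6-fold lower (log2 fold change -4.94, SE 0.19, adjusted p = 5.17e-06), and the transcription factor genes PITX1 (at least 33.6-fold), LHX2 (-5.20, SE 0.17) and BHLHE22 (-4.80, SE 0.20) were lower as well. In the other direction, PLAAT4 was at least 49.3-fold higher, the chemokine gene CCL22 was 46.7-fold higher (5.54, SE 0.35, adjusted p = 4.99e-05) and the fructose transporter gene SLC2A5 was 32.2-fold higher (5.01, SE 0.21). ALDH1A1, an aldehyde dehydrogenase (4.63, SE 0.36), and MFGE8, a secreted protein that binds apoptotic cells (5.05, SE 0.15), were also higher.

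The remaining genes with the largest change were TEX19 (5.13), SNORD13 (4.81), PPM1L (4.61) and CMTM7 (4.24) among the higher, and MAG (5.21), for which a second probe gave 1.13. Other probes of CMTM7 ranged down to 1.41. Among the lower were DSG2 (at least 21.6-fold), SCRN1 (at least 21.5-fold), PYROXD2 (at least 23.1-fold), ABHD17C (at least 22.1-fold) and SPRY2 (at least 18.4-fold). A second DSG2 probe gave -2.25 and a second CCND2 probe -5.08. DSG2 lies on chromosome 18, where 86.9% of 145 tested genes had a negative log2 fold change (48.4% of all genes placed on chromosomes), in a run of neighbours of which 23 of 25 did. SNORD13 is a small nucleolar RNA, a class of which 7 of 112 tested genes were higher and 22 lower. By contrast, 11 of 16 tested small nuclear and Y RNA genes were higher and 0 lower, with 15 of the 16 at their highest level in replicate 2 of the libraries labelled SLAMF1 shRNA.

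**Figure D1:**
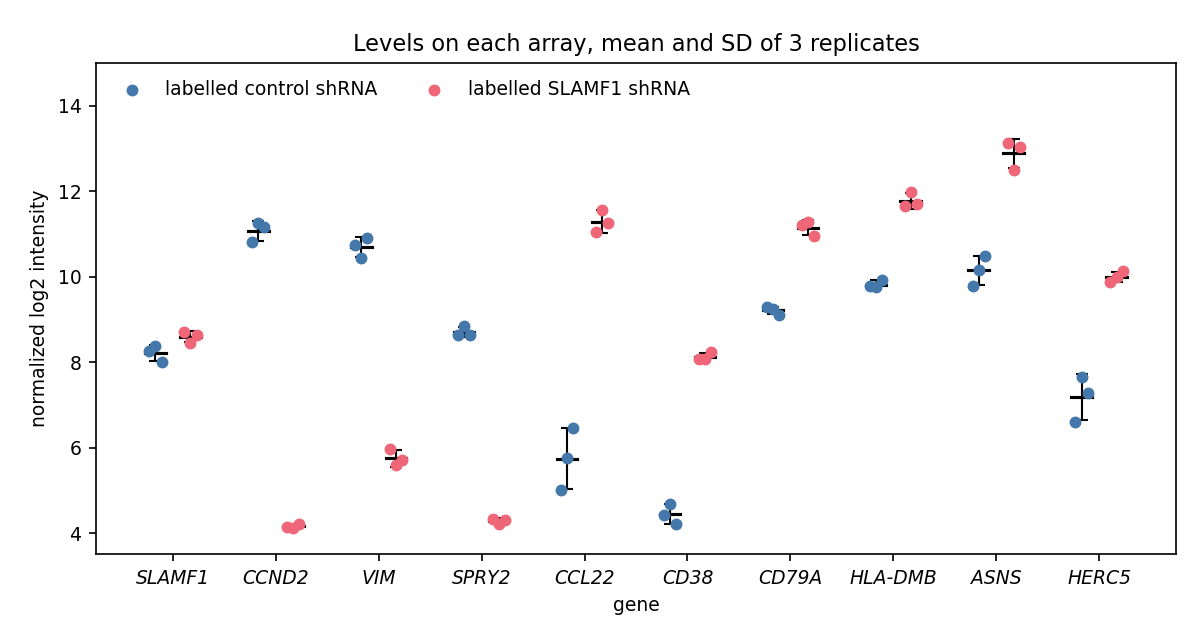
Normalized log2 intensity (y axis) of 10 genes (x axis) on each array, with points for the 6 libraries, horizontal bars for the mean and whiskers for the SD of 3 replicates. In every library labelled SLAMF1 shRNA, CCND2, VIM and SPRY2 are lower and CCL22, CD38, CD79A, HLA-DMB, ASNS and HERC5 higher than in any control, and SLAMF1 is higher by a small margin (8.44 to 8.70 against 8.01 to 8.38).

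Of 10832 genes tested, 1400 were higher and 1269 lower in the libraries labelled SLAMF1 shRNA (limma, adjusted p under the threshold of 0.05), of which 806 and 672 differed by at least 2-fold. The share of higher genes among the calls was 52.5% and was 42.5% with median centring. The counts moved with single arrays: 2103 higher and 1889 lower without replicate 2 of the libraries labelled SLAMF1 shRNA, which included all 1400 and all 1269; 851 higher without control replicate 1; 823 and 732 without control replicate 2; 675 and 622 without control replicate 3; and 795 lower without replicate 3 of the libraries labelled SLAMF1 shRNA.

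Replicates 1 and 3 of the libraries labelled SLAMF1 shRNA correlated at 0.994, whereas replicate 2 correlated with them at 0.928 and 0.942. Control replicates correlated at 0.981 to 0.992 and arrays of different labels at 0.849 to 0.932, all across the tested genes, which are not independent replicates.

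**Figure D2:**
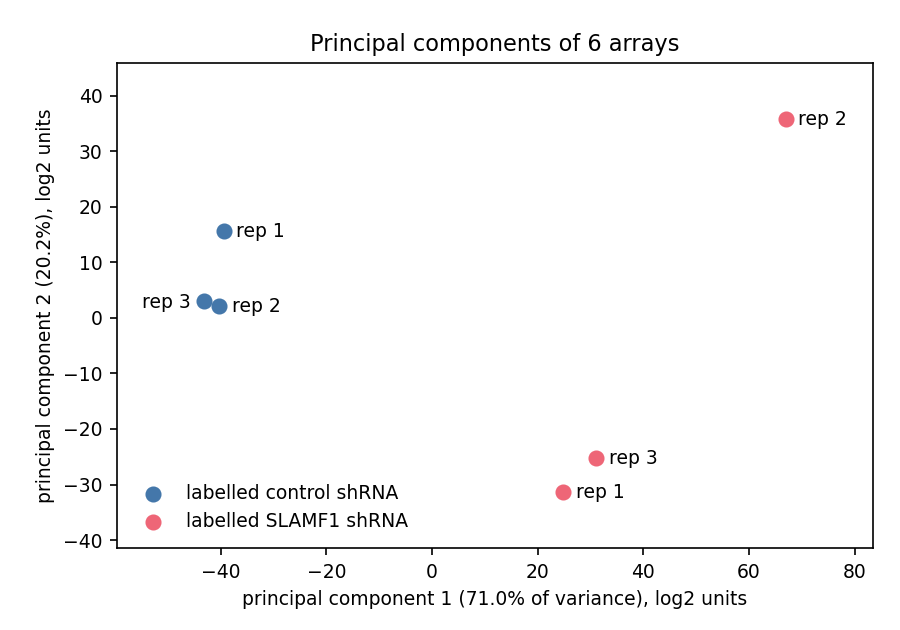
Scores of the 6 arrays on the first 2 principal components of the tested genes, in log2 units, with the share of variance in the axis labels (71.0% and 20.2%). The 2 sets of libraries part along the first component. Replicate 2 of the libraries labelled SLAMF1 shRNA lies apart from replicates 1 and 3 along the second and also along the first (66.9 against 24.9 and 31.1).

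Genes of the chemotaxis theme of the title went both ways. Of 15 tested chemokine and chemoattractant receptors, 4 were higher and 3 lower, and 7 and 3 adjusted over the list alone. Leaving out replicate 2 of the libraries labelled SLAMF1 shRNA also gave 7 higher and 3 lower. ACKR3, a scavenger receptor for CXCL12, was higher (log2 fold change 2.58, SE 0.29), and the prostaglandin receptor gene PTGER4 (-2.23, SE 0.19) and the chemokine receptor gene CXCR3 (-1.89, SE 0.18) were lower. CXCR4, singled out after its values were seen, gave 0.56 with a standard error of 0.74 (adjusted p = 0.615), and a second probe gave 1.67. Without replicate 2 of the libraries labelled SLAMF1 shRNA, in which it read 5.92, CXCR4 was called higher at 1.58 (adjusted p = 1.26e-05). The list did not pass camera (adjusted p = 0.367) but passed fry as higher (adjusted p = 0.000438).

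Of 9 tested chemokines, 3 were higher and 3 lower, and 3 and 3 adjusted over the list alone (camera adjusted p = 0.938). CCL22 rose as described, and CXCL10 (-2.94, SE 0.27) and CCL3 (-2.59, SE 0.42) fell. Of 24 tested adhesion molecules and integrins, 9 were higher and 5 lower, and 9 and 5 adjusted over the list alone (camera adjusted p = 0.236; fry adjusted p = 0.0029). The ectoenzyme gene CD38 (3.68, SE 0.18), the integrin gene ITGAL (2.09, SE 0.25) and ICAM2 (1.81, SE 0.30) were higher.

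Autophagy genes also went both ways. Of 39 tested, 8 were higher and 3 lower, and 9 and 3 adjusted over the list alone (camera adjusted p = 0.466; fry adjusted p = 0.0117). For scale, 24.6% of all tested genes were called, and by camera the list did not differ from the rest. WIPI1 (1.85, SE 0.17) and WIPI2 (1.54, SE 0.31), which bind the forming autophagosome, were higher. PIK3C3, the lipid kinase that starts autophagosome formation, was lower (-1.60, SE 0.16) and lies in the same run of neighbours on chromosome 18 as DSG2. BECN1, chosen after its values were seen, gave -0.55 (SE 0.28, adjusted p = 0.195), and -0.26 without replicate 2 of the libraries labelled SLAMF1 shRNA. Of 27 lysosome genes, 6 were higher and 3 lower, and 10 and 3 adjusted over the list alone (camera adjusted p = 0.174; fry adjusted p = 0.0143), with GUSB (1.48, SE 0.17) and CTSB (1.47, SE 0.28) higher and CTSC (-1.99, SE 0.37; other probes up to -0.65) lower. Lysosome genes numbered 11 higher and 3 lower without replicate 2 of the libraries labelled SLAMF1 shRNA. Of 29 vesicle traffic and SNARE genes, 2 were higher and 0 lower, and 0 and 0 adjusted over the list alone (camera adjusted p = 0.938). The 2 higher genes were STXBP2 (1.29, SE 0.33) and RAB5B (0.67, SE 0.17). Leaving out replicate 2 of the libraries labelled SLAMF1 shRNA gave 3 higher and 3 lower. The STXBP2 call was lost without any 1 control replicate (adjusted p = 0.0925, 0.0872 and 0.0895), with no background correction (0.0732), an offset of 50 (0.0505), the second deposited table (0.0646) and no filter on dim probes (0.0825), and its log2 fold change was 0.87 without replicate 2 of the libraries labelled SLAMF1 shRNA. The RAB5B call was lost without any 1 control replicate (adjusted p = 0.0664, 0.0720 and 0.0572) or replicates 1 (0.0627) or 3 (0.0650) of the other set, with median centring (log2 fold change 0.42, adjusted p = 0.207) and with the replicate number as a block (0.0638). The median of this list was -0.01 and its mean 0.03.

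Several genes of B cells were higher, while others were lower, among them MS4A1, TCL1A and IGLL1, which were chosen after their values were seen and are given further below. Of 23 tested B cell identity genes, 10 were higher and 2 lower, and 11 and 2 adjusted over the list alone (camera adjusted p = 0.00286; adjusted p = 0.168 with an estimated correlation). The transcription factor gene LEF1 was at least 11.6-fold higher, BCL6 rose by a log2 value of 2.20 (SE 0.17) and VPREB3 by 1.79 (SE 0.24). With a detection p under 0.01 on all arrays the list no longer passed (adjusted p = 0.0586, against 0.000365 to 0.168 over all alternatives). Of 24 B cell receptor signalling genes, 5 were higher and 3 lower, and 6 and 3 adjusted over the list alone (camera adjusted p = 0.618), with CD22 (2.37, SE 0.32), CD79A (1.93, SE 0.17; other probes from 0.51 to 2.11) and CD79B (1.83, SE 0.23) higher. Of 18 plasma cell genes, 8 were higher and 2 lower, and 10 and 2 adjusted over the list alone (camera adjusted p = 0.0102; adjusted p = 0.168 with an estimated correlation). PIM2 (3.66, SE 0.23) and JCHAIN (2.72, SE 0.45) were higher, while SDC1, the plasma cell marker CD138, was lower by 1 probe (-3.14, SE 0.24) and gave -0.02 by another.

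Part of the tested antigen presentation genes were higher. Of 10 tested MHC class II genes, 6 were higher and 0 lower, and 8 and 0 adjusted over the list alone (camera adjusted p = 5.87e-05; adjusted p = 0.117 with an estimated correlation). They included HLA-DOA (2.08, SE 0.19), HLA-DMB (1.96, SE 0.17) and HLA-DMA (1.70, SE 0.16), whose products load peptide or regulate loading. Of 14 MHC class I genes, 8 were higher and 0 lower, and 10 and 0 adjusted over the list alone (camera adjusted p = 0.000945; adjusted p = 0.168 with an estimated correlation). HLA-F (1.75, SE 0.22), HLA-B (1.39, SE 0.16) and HLA-G (1.32, SE 0.26) were among them, and the HLA-G call was lost without control replicate 3 (adjusted p = 0.0541). HLA genes such as HLA-DMB and HLA-G lie on chromosome 6 between SOX4 and CILK1. All runs of 25 neighbouring tested genes taken there had a median log2 fold change above 0. The median was 0.61 from HLA-DOB to DAXX (3 of 25 lower) and 0.46 from RING1 to SNRPC (5 of 25 lower). Whether the MHC lists rose beyond their neighbours was not tested, so a shift of the region cannot be told apart. Of 32 interferon-stimulated genes, 14 were higher and 1 lower, and 16 and 1 adjusted over the list alone (camera adjusted p = 0.000945; adjusted p = 0.536 with an estimated correlation). ISG20 (2.89, SE 0.27), HERC5 (2.82, SE 0.27) and OAS2 (2.75, SE 0.50) led them, and the OAS2 probes ranged down to 0.51.

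The largest shift of a list was in genes of the amino acid response, targets of the transcription factor ATF4. Of 22 tested, 16 were higher and 1 lower, and 17 and 1 adjusted over the list alone, with a median log2 fold change of 1.39 (camera adjusted p = 5.0e-08; adjusted p = 0.117 with an estimated correlation). CEBPB rose by 2.92 (SE 0.17) on the log2 scale, the asparagine synthetase gene ASNS by 2.74 (SE 0.25) and the pseudokinase gene TRIB3 by 2.64 (SE 0.17). Of 19 endoplasmic reticulum stress genes, 2 were higher and 1 lower, and 2 and 1 adjusted over the list alone (camera adjusted p = 0.633). Leaving out replicate 2 of the libraries labelled SLAMF1 shRNA gave 4 higher and 4 lower. DDIT3 (2.89, SE 0.34) and DNAJB9 (1.74, SE 0.18) were higher, and DNAJB11 was lower (-0.74, SE 0.16), a call lost without control replicate 2 (adjusted p = 0.0501), control replicate 3 (0.0675) or replicate 3 of the other set (0.0562).

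Of 26 glycolysis and hypoxia genes, 12 were higher and 1 lower, and 12 and 1 adjusted over the list alone (camera adjusted p = 0.00535; adjusted p = 0.536 with an estimated correlation). The related enzymes PFKFB4 (4.19, SE 0.49) and PFKFB3 (-3.49, SE 0.28), which set the level of an activator of glycolysis, moved in opposite directions, and a second PFKFB3 probe gave -1.0. ALDOC was higher (2.29, SE 0.30). Of 20 NADPH oxidase and redox genes, 3 were higher and 6 lower, and 3 and 8 adjusted over the list alone (camera adjusted p = 0.185), with HMOX1 (-2.61, SE 0.36) and NQO1 (-1.98, SE 0.20) lower and the cystine transporter gene SLC7A11 higher (1.81, SE 0.21). Of 17 cholesterol synthesis genes, 0 were higher and 1 lower by limma, and 0 and 0 adjusted over the list alone (camera adjusted p = 0.618). CYP51A1 was that gene (-0.90, SE 0.23), and the call was lost without control replicate 2 (adjusted p = 0.0645), control replicate 3 (0.073) or replicates 1 (0.0503) or 3 (0.0691) of the other set.

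The immediate early and MAP kinase list was lower. Of 22 tested genes, 1 was higher and 7 lower, and 1 and 7 adjusted over the list alone (camera adjusted p = 0.00924; adjusted p = 0.168 with an estimated correlation; adjusted p = 0.566 with a detection p under 0.01 on all arrays, which removes genes undetected on any array; 0.000156 to 0.566 over all alternatives). The members with the largest change, SPRY2, SPRED1 (-3.55, SE 0.19) and DUSP4 (at least 2.95-fold), are known as negative regulators of this pathway. Of 21 NF-kappaB targets, 3 were higher and 4 lower, and 5 and 4 adjusted over the list alone (camera adjusted p = 0.938). Its median was 0.14, its mean -0.04, and fry gave the lower direction. Without replicate 2 of the libraries labelled SLAMF1 shRNA its median was 0.01, with 5 higher and 5 lower. TNF (-2.52, SE 0.17) and LTA (-1.35, SE 0.23) were lower and EBI3 was higher (2.11, SE 0.20).

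Of 34 proliferation genes, 1 was higher and 4 lower, and 0 and 3 adjusted over the list alone (camera adjusted p = 0.0664; 0.00601 to 0.672 over its alternatives). The list passed as lower in 8 alternatives: without control replicate 1 (adjusted p = 0.0274) or replicates 1 (0.0343) or 3 (0.0261) of the other set, with no background correction (0.0313), an offset of 50 (0.0380), the second deposited table (0.0332), no filter on dim probes (0.00601) and a detection p under 0.01 on all arrays (0.0421). It did not pass without replicate 2 of the libraries labelled SLAMF1 shRNA (adjusted p = 0.366). TYMS (-1.47, SE 0.23), which also lies on chromosome 18, and KIF20A (-1.43, SE 0.33) were lower and FOXM1 higher (1.07, SE 0.29). The KIF20A call was lost without control replicate 2 (adjusted p = 0.0656) or 3 (0.0799) and with no filter on dim probes (0.0573). The FOXM1 call was lost without any control replicate (adjusted p = 0.103, 0.0983 and 0.0909) or replicate 3 of the other set (0.0516), with no background correction (0.0640), the second deposited table (0.0572) and no filter on dim probes (0.0825), and its log2 fold change was 0.73 without replicate 2 of that set. Of 13 p53 targets, 1 was higher and 3 lower, and 2 and 4 adjusted over the list alone (camera adjusted p = 0.635), with TP53INP1 higher (2.15, SE 0.19; another probe 2.74) and TIGAR (-1.29, SE 0.27) and CDKN1A (-1.08, SE 0.26) lower. TIGAR lost its call without control replicate 1 (adjusted p = 0.0502) or 3 (0.0575), and CDKN1A without control replicate 2 (0.0742) or 3 (0.0829) or replicate 3 of the other set (0.0611), with no filter on dim probes (0.0530) and with the replicate number as a block (0.0552). Of 25 BCL2 family and apoptosis genes, 3 were higher and 3 lower, and 3 and 3 adjusted over the list alone (camera adjusted p = 0.938). CFLAR was higher (1.37, SE 0.29; lost without control replicate 1, adjusted p = 0.0593, or 3, 0.0597), CYCS was lower (-1.23, SE 0.25), and MCL1 was higher by 1 probe (1.19, SE 0.18) and gave -0.76 by another, with the call lost for the mean of its probes (0.22).

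Of 6 tested genes of the SLAM family and its adaptors, SLAMF1 left out, 2 were higher and 0 lower, and 2 and 0 adjusted over the list alone. They were LY9 (1.91, SE 0.17; another probe 1.12) and CD48 (1.09, SE 0.16). The list did not pass camera (adjusted p = 0.0998) and passed without replicate 3 of the libraries labelled SLAMF1 shRNA (adjusted p = 0.0453), with a detection p under 0.01 on all arrays (0.0353) and by fry (0.00282, against 0.00282 to 0.383 over all alternatives). Of 36 ribosomal protein genes, 0 were higher and 3 lower by limma, and 0 and 3 adjusted over the list alone (camera adjusted p = 0.674): RPL29 (-1.45, SE 0.24), RPL34 (-1.34, SE 0.28; another probe -0.12, and the call lost at -0.73 for the mean of its probes, adjusted p = 0.0797) and RPS6 (-0.89, SE 0.22), the last of which lost its call without any 1 control replicate (adjusted p = 0.0742, 0.0609 and 0.0605) or replicate 3 of the other set (0.0636), and with median centring (0.0529).

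Markers of other blood cells were examined too. Of 9 tested T and NK cell markers, 2 were higher and 3 lower, and 2 and 4 adjusted over the list alone (camera adjusted p = 0.633), with a median of -0.30 and a mean of 0.20. The median was -0.52 without replicate 2 of the libraries labelled SLAMF1 shRNA. PRF1 (2.67, SE 0.23) and NKG7 (1.98, SE 0.41) were higher and IL7R at least 1.55-fold lower. The NKG7 call was lost without control replicate 1 (adjusted p = 0.0502) or 3 (0.0592), with no background correction (log2 fold change 0.78, adjusted p = 0.0849) and with the second deposited table (0.88, adjusted p = 0.0726). Of 6 myeloid markers, 1 was higher and 1 lower, and 1 and 1 adjusted over the list alone (camera adjusted p = 0.938), with a median of 0.03 and a mean of -0.02. Their median was -0.11 without replicate 2 of the libraries labelled SLAMF1 shRNA. CSF1R was at least 1.53-fold higher. TYROBP was at least 1.23-fold lower, a call lost without control replicate 1 (adjusted p = 0.0619), 2 (0.0774) or 3 (0.099) or replicates 1 (0.0712) or 3 (0.0894) of the other set, with no background correction (0.0723), an offset of 50 (0.0866), the second deposited table (0.0664) and the replicate number as a block (0.0743).

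In total, 7 of the 27 lists were higher and 1 lower by camera with the preset correlation, also without replicate 2 of the libraries labelled SLAMF1 shRNA. With an estimated correlation 0 lists passed, the lowest adjusted p being 0.117, while fry gave 12 higher and 2 lower. The estimate lay below the preset 0.01 for MHC class II (-0.083), plasma cell (-0.052) and immediate early genes (-0.021). Their camera adjusted p still rose to 0.117, 0.168 and 0.168, so a higher correlation among members is not what removed these lists. For the other lists that had passed the estimate lay above the preset. It was 0.016 for MHC class I, 0.025 for B cell identity and 0.028 for the amino acid response. It was 0.175 for glycolysis and hypoxia and 0.298 for interferon-stimulated genes. Since adjusted p also rose where the estimate was below the preset, its rise in these lists is not by itself evidence of correlated members.

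**Figure D3:**
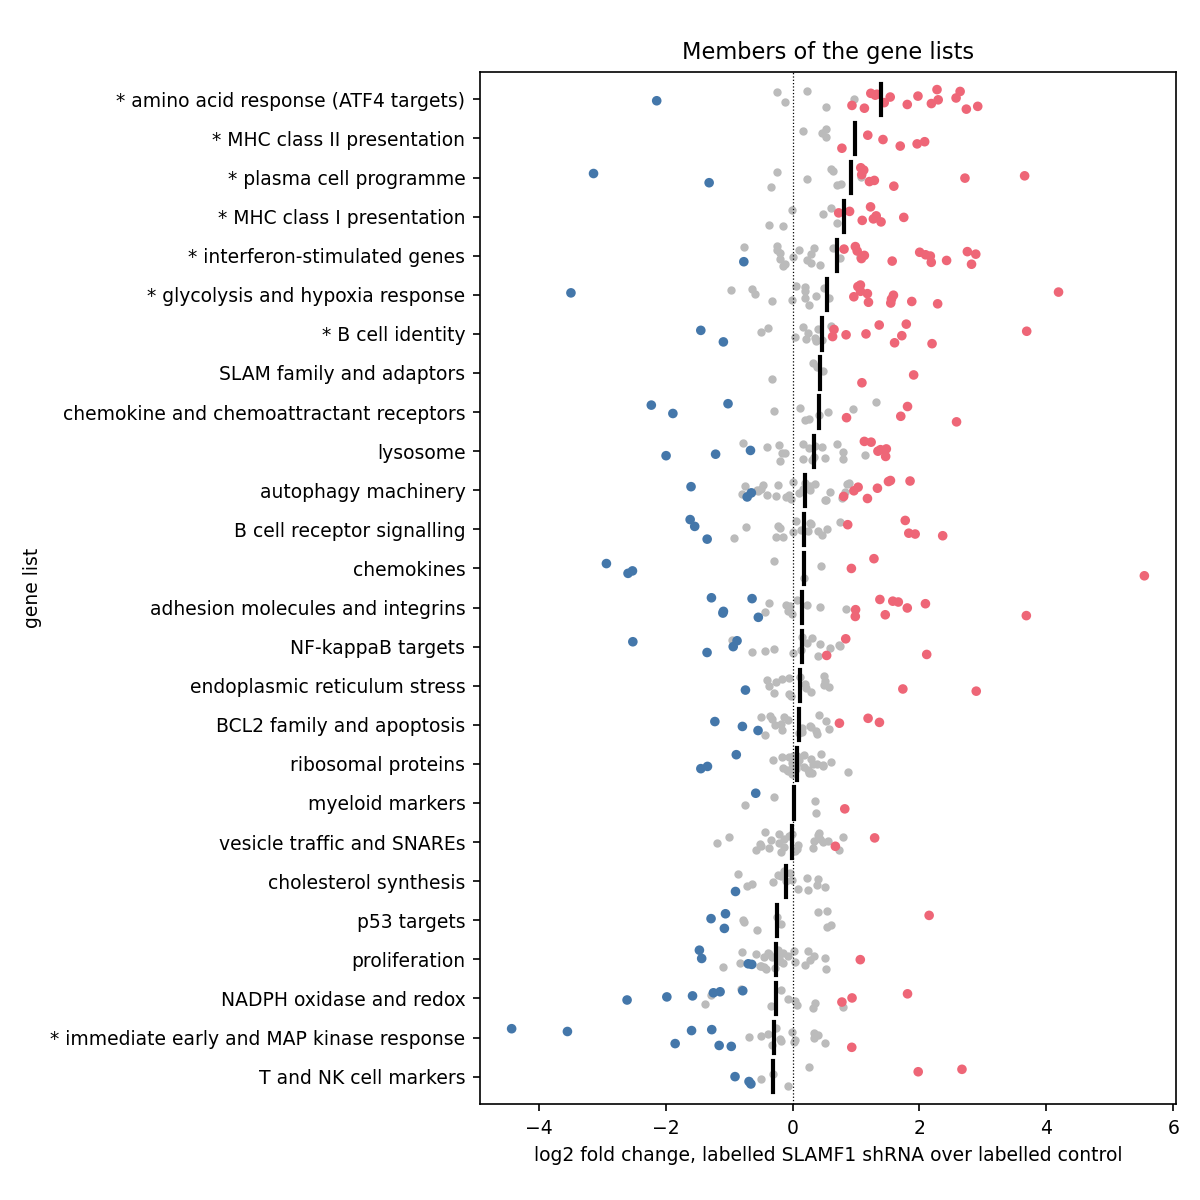
Log2 fold change (x axis) of every tested member of the gene lists reported here (y axis), with coloured points for members past the per-gene threshold, grey points for the rest and a black bar for the list's median. Lists marked with an asterisk passed camera with the preset correlation. The amino acid response list has the highest median, 1.39, and no marked list passed with an estimated correlation.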

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

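Of the values of 93 named genes, SLAMF1 left out, 1577 kept their call, 69 fell short of the threshold and 0 changed direction under the alternatives. With each probe tested separately these compare the probe of the main fit, and 1 other probe, of MCL1, had the opposite sign (-0.76, adjusted p = 0.504). With a detection p under 0.01 on all arrays 28 of the 93 had no value. The 93 genes were picked for passing the main fit with large changes, so a high share of kept calls was largely set by that choice. Of all 2669 calls of the main fit, 1293 were kept without control replicate 3 and all with array weights. SLAMF1 passed the threshold as higher with array weights and without replicate 2 of the libraries labelled SLAMF1 shRNA. Gene lists gave 487 unchanged, 16 newly passing and 10 lost calls. The numbers of genes changed by at least 2-fold were 274 higher and 239 lower with no background correction, 469 and 384 with an offset of 50, and 323 and 275 with the second deposited table, settings that by construction add to or leave in the background and so compress folds. Median centring gave 814 higher, 534 of them by at least 2-fold, with the median of all genes moved to -0.14 from 0.02. A detection p under 0.01 on all arrays gave 830 lower and 437 at least 2-fold lower out of 7809 genes tested, since genes undetected in 1 group are left out. Array weights gave 2758 higher and 2618 lower and SLAMF1 at 0.49 (limma adjusted p = 0.00735), with replicate 2 of the libraries labelled SLAMF1 shRNA weighted 0.123. Lists lower numbered 2 with no background correction, an offset of 50, the second deposited table and no filter on dim probes. An estimated correlation gave 0 lists higher and 0 lower, and fry 12 and 2. The cause of the other changes was not tested. With each array left out in turn, 675 to 2103 genes were higher and 622 to 1889 lower, 586 to 989 and 521 to 826 by at least 2-fold, SLAMF1 lay at 0.28 to 0.46, and 7 to 8 lists were higher and 1 to 2 lower. No list values were computed with each probe tested separately. The mean of a gene's probes ended the calls of MCL1 (0.22) and RPL34 (-0.73). Signal over background limits dim genes, for which a fold rests on the offset.

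Replicate numbers did not pair the samples: the correlations of same-numbered deviations were -0.205, -0.140 and 0.210, and 2 of 6 arrays were closest to their own number. With the replicate number as a block, 1107 genes were higher and 961 lower, 2068 in all, of which 2005 were shared with the fit without it, and SLAMF1 differed by 0.38 (adjusted p = 0.242).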

Other observations

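The genes of this part were chosen after their values were seen, and directions are those of the labels. They form no list fixed beforehand and were not tested as groups. CD52, the target of alemtuzumab, was 8.25-fold lower in the libraries labelled SLAMF1 shRNA (log2 fold change -3.04, SE 0.30, limma adjusted p = 0.000398). MS4A1, which encodes CD20, the target of rituximab, gave -1.45 (SE 0.43, adjusted p = 0.0422), with adjusted p up to 0.144, without control replicate 2, when 1 array was left out. Its size rests in part on replicate 2 of the libraries labelled SLAMF1 shRNA (log2 level 5.89 against 7.68 and 7.29), without which it was -0.91 (adjusted p = 0.00288). The drug efflux pump gene ABCB1 was higher (2.94, SE 0.23; another probe 1.05), as was the DNA repair gene MGMT (2.92, SE 0.46). MGMT had a log2 level of 9.54 in replicate 2 of the libraries labelled SLAMF1 shRNA, against 7.88 and 7.92. Without that replicate it gave 2.37 (limma adjusted p = 9.74e-06). BCL2, the target of venetoclax, gave -0.54 (SE 0.17, adjusted p = 0.0466), with adjusted p up to 0.133, without replicate 3 of the libraries labelled SLAMF1 shRNA, when 1 array was left out. BCL2 lies on chromosome 18, where the median of all 145 tested genes was -0.66, so its value is no larger than that of its chromosome. TCL1A, an oncogene of B cell leukaemia, was at least 5.43-fold lower and the surrogate light chain gene IGLL1 at least 7.21-fold lower.

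FSCN1, an actin bundling protein, was 17.1-fold lower (-4.09, SE 0.28), and CAV1 was 12.8-fold lower (-3.68, SE 0.28; another probe -1.74). CD44 (1.46, SE 0.17) and ITGB1 (1.58, SE 0.17) were higher, with second probes at 0.72 and 0.46. RUNX2 was at least 9.14-fold higher by 1 probe and 0.60 on the log2 scale by another. EOMES (-3.30, SE 0.36) and TBXT (-2.56, SE 0.19; another probe -1.28) were lower, and HOXB2 was at least 6.32-fold lower.

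Of the tests below, those of SLAMF1, of replicate 2, of the splits and of the order of genes by chance were chosen after the result was seen, and the remaining tests of neighbouring genes before. The real split of the 6 arrays gave 2669 called genes and was 1 of 10 splits with a count as large, the highest other giving 0. With 10 splits no share under 0.05 can be reached.

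The SLAMF1 probe was not lower in the libraries labelled SLAMF1 shRNA. Scaling or background correction hiding a fall of at least 2-fold is argued against, since the lowest lower 95% limit of the log2 difference over 5 other sources of values was -0.65. Exchanged labels with at least 2-fold silencing are also argued against if the probe follows the silenced transcript. The upper 95% limit of the difference was 0.79, below 1. Exchanged labels with weaker silencing lie within that interval (-0.03 to 0.79) and cannot be told apart. A probe that does not follow the silenced transcript cannot be told apart from a lack of silencing at the RNA level, because only 1 SLAMF1 probe was named. For a smaller fall of the signal of this probe the lower 95% limit was -0.03 in the main fit and -0.06 to 0.02 with 4 of the 5 other sources. Median centring (0.10, SE 0.27) leaves the most room. The limits of the other sources use the 4 residual degrees of freedom alone, which gives wider intervals than limma's own in the main fit. They are therefore not on the same footing. Silencing that acts on the protein without lowering the RNA was not tested.

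Replicate 2 of the libraries labelled SLAMF1 shRNA stood apart from the other 2. Control RNA mixed into it would draw it toward the controls, but over genes called without it and changed by at least 2-fold its distance from them was 1.09 (95% interval 1.05 to 1.13) of that of replicates 1 and 3 for 737 higher genes and 1.03 (1.01 to 1.05) for 590 lower genes. Weak signal is argued against as the whole cause, since among bright genes its deviations spread 1.55 times (1.44 to 1.66) as widely as those of the next array. These intervals come from resampling genes, which are not independent replicates, and do not measure the spread between samples. Loss of long transcripts may play a part, with a Spearman correlation across genes of -0.25 between deviation and genomic span, but control replicate 1 gave -0.21 and span is not transcript length, so this cannot be told apart. A biological difference of that sample was not tested.

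Windows of 25 neighbouring tested genes were taken in steps of 5 genes, so adjacent windows share most genes and are not separate observations. All 25 windows of chromosome 18 had a median log2 fold change below 0 (-0.31 to -1.22, with 18 to 25 of the genes lower), the lowest from DSC3 to KATNAL2. Only that 1 of the 25 went beyond the highest median of the shuffled orders, 0.876 in size. On chromosome 18, 86.9% of genes were lower, against 48.4% of all genes placed. A run on chromosome 6 from SNX3 to TSPYL1, which holds FOXO3 (-3.97) and AMD1 (-2.23), had -1.08, with 21 of 25 lower. This run is 1 of 4 overlapping windows, between CRYBG1 and FAM184A, that went beyond the highest shuffled median among the 115 of chromosome 6. Over that whole chromosome 50.7% of 598 genes were lower, a share that joins stretches going opposite ways. Every window from SDHAF4 to FAM120B had a median below 0, with -0.73 from HIVEP2 to DCPH1 (23 of 25 lower) and -0.71 from TAGAP to FAM120B. Every window from SOX4 to CILK1 had a median above 0, up to 0.61 from HLA-DOB to DAXX. No single window the other way went beyond the shuffled medians: the highest, from ZBTB43 to COQ4 on chromosome 9, had 0.81, with 2 of 25 lower. That bound applies to single windows and cannot judge a smaller shift spread over a chromosome. On chromosome 19 30.4% of 754 genes were lower and 5 of 146 windows lay below 0. On chromosome 9 it was 35.6% of 441 genes and 18 of 84 windows. Whether such upward shifts exceed chance was not tested. For the lowest window of chromosome 18 and that of chromosome 6, 0 of 100 shuffled orders reached the larger median, which argues against chance order. Replicate 2 alone is argued against by a smaller median of 1.0 in size without it (highest shuffled 0.63). A trend with gene span is argued against by 1.18 after its removal (highest shuffled 0.785). At least 84% of the genes of each of these 2 windows were lower, but the windows were picked by their medians, so this decides nothing about a loss of DNA copies. Copies were not measured, and such a loss, silencing of the regions and an effect of the shRNA cannot be told apart.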
